A study of Arabidopsis thaliana with 4 samples.

How the data were processed

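Gene expression was measured on 4 Affymetrix ATH1 arrays, an oligonucleotide array of Arabidopsis thaliana in which each transcript is read by a set of probes (a probe set). The total RNA came from whole seedlings at developmental stage 1.02, raised at 20 °C and 80% humidity with 16 h of light per day. The labels put 2 arrays in the Col-0 wild type group and 2 in the group called a complete knockout of CDB1 in the Col-0 background. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

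The deposited table holds 1 linear intensity value per probe set and array. The authors made these signals with MAS5, the Affymetrix method that summarises matching against mismatching probes and scales each array, per the submitters' processing notes. The MAS5 version, its settings and its detection calls are not given in the sources used here. The values bear out the scaling: the trimmed mean (without the lowest and the highest 2% of probe sets) lay between 99.5 and 100.0 on the 4 arrays, and the array medians were 47.9 to 50.6. The values run from 0 to 4620, and they are neither logged nor centred per probe set. For arrays, precision is limited by their number, here 2 per group. No pair of replicates was a copy: of 22746 probe sets, 178 had equal values on the wild type arrays and 246 on the knockout arrays.

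The 64 control probe sets were set aside, leaving 22746. Probe sets whose mean over the 4 arrays lay below the 30th percentile were left out, which set a brightness floor at a mean signal of 19.5 and left 15924 probe sets. Signals were used as deposited and transformed to log2(signal + 16), so a fold change is on that scale and understates the change of dim genes. The pseudocount was 16. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided), with Benjamini-Hochberg adjustment over the 15924 probe sets and a threshold of 0.05 on the adjusted p. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so the statements rest on the variance that limma shares across probe sets (8.82 prior degrees of freedom). The procedure was tested on simulated data for this comparison, with 200 of 15924 probe sets changed. It recovered 6% of those changed by 0.5 on the log2 scale, 82% of those changed by 1 and 100% of those changed by 1.5 or by 2. There were 10 false calls among 154, and none when nothing was changed. The simulated noise was independent between arrays and probe sets, with variances drawn from the prior that limma fitted. In the real arrays the replicate differences of the 2 groups were correlated (-0.301). The simulation did not copy this, so these rates may not hold for the real arrays.

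Gene names came from the annotation table of the array's platform, which can be old. Of the 22746 probe sets, 13513 had 1 gene symbol, 503 had several and 8730 were not listed, so they are unnamed here. Symbols were updated through gene numbers for 13436 probe sets against the RefSeq annotation of assembly TAIR10.1. The build used for the array design is not given in the sources used here, so no coordinates are printed, and chromosomes and neighbouring genes are those of TAIR10.1. Where several probe sets named a gene, the brightest stood for it in the gene lists.

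The design, the alternatives, 21 gene lists with 266 members and the rule for named genes were fixed before the data were examined. The rule named up to 15 genes in each direction with the largest change among those past the threshold, with a single gene symbol and no overlap between groups, and up to 4 tested members of each list with the largest change. The annotation table named a probe set for 28 of the 266 list members, of which 21 were bright enough to test. No list reached the 5 tested members set as the minimum, so the planned list test (camera) was not run on them. In its place, 30 groups of genes were tested that were added after the data were seen: 28 groups sharing a symbol stem with at least 6 tested genes, the plastid-encoded genes, and 12 rapidly induced wound and elicitor response genes. They were tested with camera (preset correlation of 0.01, and an estimated correlation) and with fry, with Benjamini-Hochberg adjustment over the 30. Values are given for 4 of these groups, and those of the others are not reported here.

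Alternatives were quantile normalization, median centring, pseudocounts of 1 and 64, no filter and a filter at the 50th percentile, eBayes without the trend, the replicate number as a block, each array left out in turn, and other thresholds. A filter at the 10th percentile and a crossed pairing of the replicates were added after seeing the data. The replicate numbers are shared by the groups, but nothing says that they mark a shared batch or day. The targeted gene could not be checked, since neither annotation table used here pairs the name CDB1 with a probe set or locus.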

Results

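Transcript levels were compared between whole Arabidopsis seedlings of the Col-0 wild type (2 arrays) and of a line labelled as a complete knockout of CDB1 (2 arrays). The series title speaks of a protein that binds Polycomb, the repressive chromatin machinery that keeps developmental genes silent. The design asks which transcripts differ in the line without CDB1. The seedlings were at stage 1.02 and were grown on plates at 20 °C under 16 h days. Values are MAS5 signals in arbitrary units, scaled by the authors to a trimmed mean near 100 per array, and 15924 probe sets were bright enough to be tested. The level of CDB1 itself could not be given, because no annotation used here ties the name to a gene.

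Arrays of the same group were hardly more alike than arrays of different groups. The correlation across tested probe sets was 0.977 between the wild type arrays and 0.982 between the knockout arrays. Between groups it ranged from 0.975 to 0.984, and the highest value joined wild type replicate 1 to knockout replicate 2. The SD of the log2 difference between 2 arrays was 0.273 within the wild type, 0.242 within the knockout and 0.229 to 0.286 between groups. These correlations are across probe sets, which are not independent replicates.

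A small set of transcripts differed in the knockout, and that of AT5G27280 differed most. AT5G27280, on chromosome 5, which encodes a protein with a Zim17-type zinc finger, fell from a signal of 199 ± 33.4 (SD, n = 2) in wild type to 9.25 ± 7.28 (SD, n = 2) in the knockout. Both knockout arrays, at 4.1 and 14.4, were below the brightness floor of 19.5. STZ (also known as ZAT10), a stress-inducible zinc finger repressor of transcription, was 2.02-fold lower, while the plant defensin gene PDF1.2b and the jasmonate-regulated gene JRG21 rose, by log2 fold changes of 0.83 to 1.76 and 0.59 to 1.98 over the alternatives. In all, 51 of 15924 probe sets passed an adjusted p of 0.05 in limma, 27 of them higher and 24 lower in the knockout. Of these, 25 name a single gene, 14 higher and 11 lower, and these are described here. On all 51 both knockout arrays lay on the same side of both wild type arrays. That was true of 31.9% of all tested probe sets and is expected by chance of 33.3%. The 51 were called from the same 4 arrays, so this is not separate evidence for them. The count depended on single arrays and on the filter. Without wild type replicate 1 it was 87 (48 higher, 39 lower), without knockout replicate 1 it was 23 (5 higher, 18 lower), without knockout replicate 2 it was 20 (7 higher, 13 lower), and with no filter on dim probe sets it was 0.

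**Figure D1:**
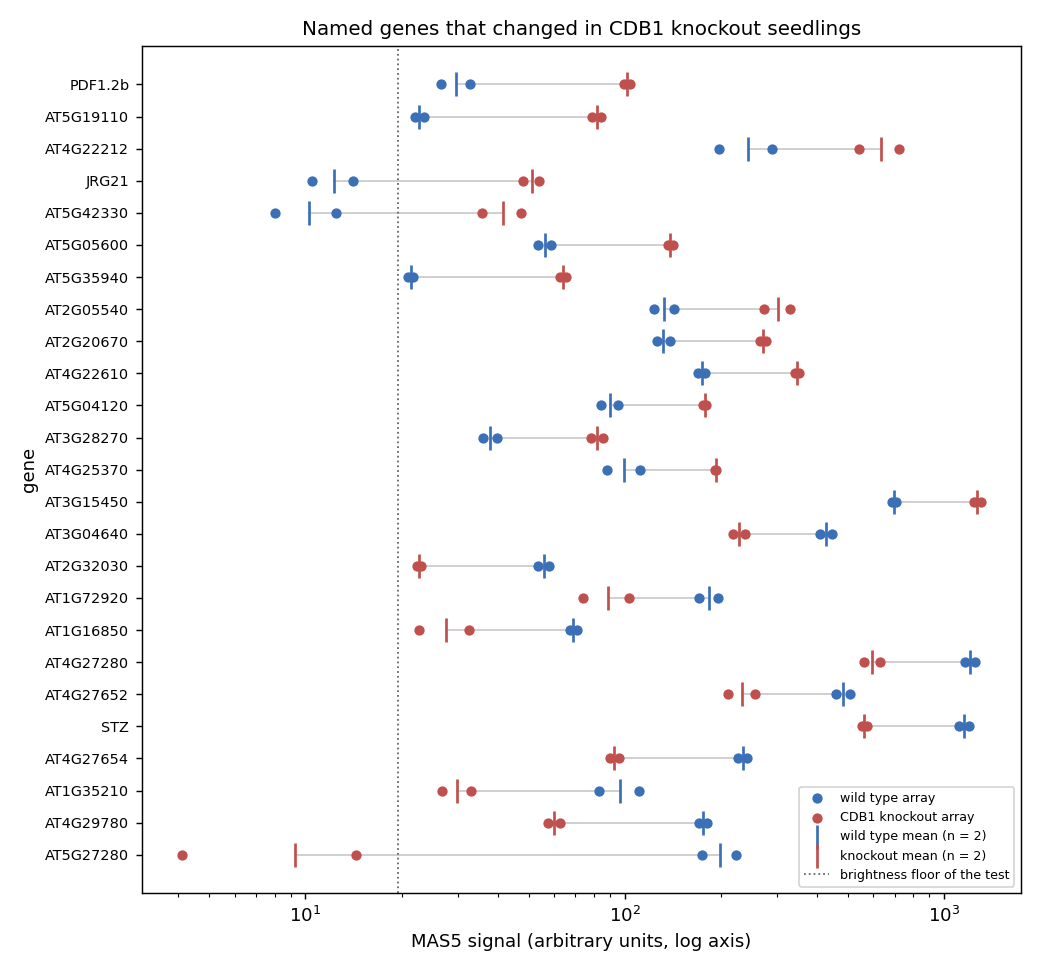
MAS5 signal (arbitrary units, log axis) of the 25 named genes that passed the test. Points are single arrays, vertical ticks are group means (n = 2), and the dotted line is the brightness floor of 19.5. Wild type and knockout arrays do not overlap for any of the 25 genes, which the rule for named genes required. AT5G27280 shows the widest gap, from 199 to 9.25.

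AT5G27280 had a log2 fold change of -3.11 (SE 0.206, 95% confidence interval -3.56 to -2.66, limma adjusted p = 0.000205), or 8.64-fold lower on the log2(signal + 16) scale. As both knockout signals were below the floor, the size of this fall is uncertain, and the log2 fold change ranged from -4.48 to -1.84 over the alternatives. AT4G29780 fell from 176 ± 6.79 to 60.2 ± 3.82 (log2 fold change -1.33, SE 0.141, limma adjusted p = 0.00391). AT1G35210 fell from 96.7 ± 19.7 to 29.9 ± 4.38, a log2 fold change of -1.29. AT4G27654 and AT4G27652, which are adjacent protein-coding genes on chromosome 4 and have separate probe sets, fell by 1.21 and 1.01 on the log2 scale. STZ was among the brightest genes that changed, at 1156 ± 54.6 in wild type and 563 ± 15.1 in the knockout (log2 fold change -1.02, SE 0.128, limma adjusted p = 0.0101). AT4G27280, which encodes a calcium-binding EF-hand protein, fell from 1207 ± 64.8 to 596 ± 47.0.

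The other 4 named genes that fell had log2 fold changes between -0.97 and -0.86. They were AT1G16850, AT1G72920 (a TIR-domain protein of the immune receptor class), AT2G32030 (an acyltransferase of the GNAT class) and AT3G04640 (a glycine-rich protein). AT1G72920 went from 184 ± 18.0 to 88.4 ± 20.5, and AT3G04640 from 427 ± 25.5 to 228 ± 14.4. The call of AT2G32030, with a limma adjusted p of 0.0499, lay at the threshold.

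Among the genes that rose, PDF1.2b went from 29.6 ± 4.38 in wild type to 102 ± 3.11 in the knockout (log2 fold change 1.37, SE 0.152, limma adjusted p = 0.00456). It was the largest named rise with all arrays and the pseudocount of 16, but not with 1 or 64. Without wild type replicate 1 AT5G19110 rose more (1.36 against 1.27). AT4G22212 rose more without wild type replicate 2 (1.59 against 1.47) and without knockout replicate 2 (1.53 against 1.35). The rest of this paragraph uses all arrays. The probe set of PDF1.2b is of the kind that can also bind related transcripts, so signal of near-identical defensin genes cannot be excluded from its value. PDF1.2, measured by its own probe set, was at 6.80 ± 4.67 and 35.6 ± 10.7, and its limma adjusted p of 0.0638 missed the threshold. AT4G22212, another small defensin-like protein gene, rose from 243 ± 64.7 to 633 ± 126. JRG21 rose from 12.3 ± 2.55 to 51.1 ± 4.17, and AT5G05600, which encodes an oxygenase of the same class that acts on jasmonate, from 56.2 ± 3.68 to 139 ± 3.54. The wild type signals of PDF1.2, of JRG21 and of AT5G42330 (10.3 ± 3.18, against 41.5 ± 8.34 in the knockout) were below the brightness floor. The sizes of these differences are therefore uncertain.

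AT5G19110, an aspartyl protease family gene, rose from 22.8 ± 1.06 to 81.6 ± 3.54 (log2 fold change 1.33). AT5G35940, a jacalin-type lectin gene, rose from 21.4 ± 0.495 to 64.1 ± 2.05, and AT2G05540, a glycine-rich protein gene, from 133 ± 13.6 to 301 ± 39.2. Rises of 0.85 to 0.96 on the log2 scale were seen for AT2G20670, AT4G22610, AT5G04120, AT3G28270, AT4G25370 and AT3G15450. Of these, AT4G22610 encodes a lipid transfer type protein, AT5G04120 a phosphoglycerate mutase family protein and AT4G25370 a subunit of the plastid Clp protease. AT3G15450 was the brightest gene that rose, from 698 ± 12.3 to 1269 ± 45.7 (log2 fold change 0.85, SE 0.126, limma adjusted p = 0.016).

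The other 26 probe sets that passed the test name no single gene in the annotation used here. One of them rose from 7.40 and 5.10 on the wild type arrays to 65.8 and 90.4 on the knockout arrays (log2 fold change 2.07, SE 0.185), where the wild type signals were below the floor and leave the size of the rise uncertain. Another fell from 319 ± 30.4 to 90.2 ± 23.7 (log2 fold change -1.67, SE 0.172). Both were singled out after their values were seen.

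**Figure D2:**
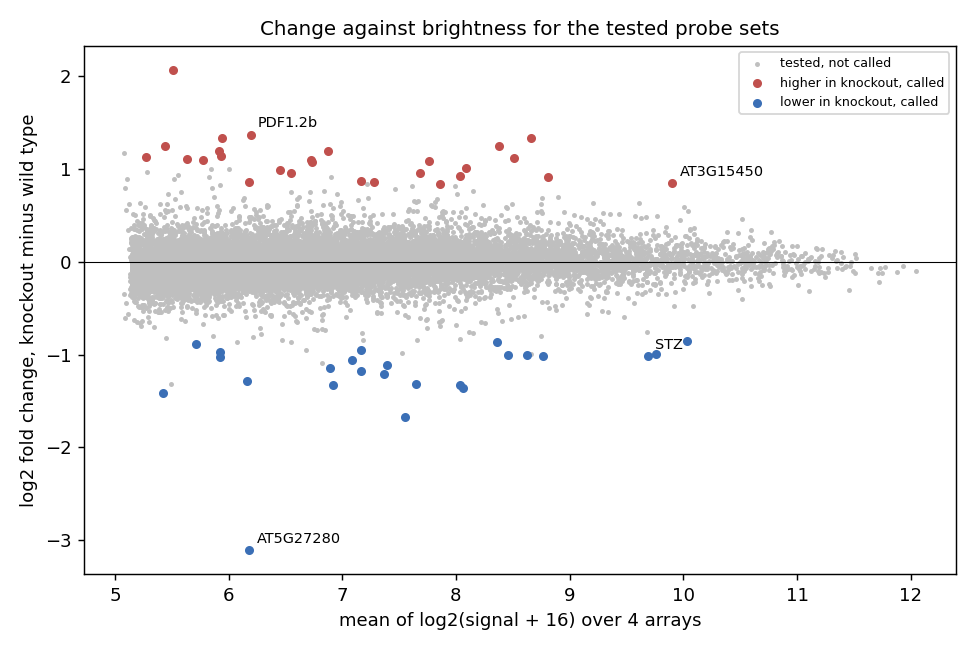
Log2 fold change (knockout minus wild type) against mean brightness, log2(signal + 16), for the 15924 tested probe sets. Coloured points are the 27 higher and 24 lower probe sets past an adjusted p of 0.05, and AT5G27280 lies furthest from 0, at -3.11.

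For the gene lists fixed beforehand, the annotation limited what could be seen. None of the 21 genes on the lists of Polycomb complex subunits and partners could be tested by name. Neither could any of the listed floral homeotic, KNOX, embryo and seed, heat shock, salicylic acid, type-A cytokinin response or phosphate starvation genes. Some of these genes may be read by unnamed probe sets that were tested. In the other lists 21 members could be tested by name, 12 above and 9 below 0. Of these 21, 1 changed, STZ, on the list of touch, wound and jasmonate response genes. Adjusted over the list alone, 3 members passed: STZ, PDF1.2 and AKINBETA1. The wild type signals of PDF1.2 were below the brightness floor, and its log2 fold change ranged from 0.49 to 2.34 over the alternatives. AKINBETA1 (log2 fold change 0.36, SE 0.149, 0.21 to 0.50 over the alternatives) was the only member of the sugar starvation list tested by name. Its limma p of 0.0358 was therefore left as it was, and no adjustment was made over the lists. Over all tested probe sets its limma adjusted p was 0.884.

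No other list member tested by name passed either adjustment. ULT1, a trithorax-type factor that opposes Polycomb silencing, was at 33.6 ± 0.212 in wild type and 29.4 ± 3.61 in the knockout (log2 fold change -0.13, 95% confidence interval -0.49 to 0.23). AGL24, a promoter of flowering, was at 19.7 ± 2.69 and 26.4 ± 2.55 (log2 fold change 0.25, interval -0.14 to 0.64). GI, of the circadian clock, had a log2 fold change of -0.18, and the replication gene PRL (also known as MCM7) one of 0.02. The photosynthesis genes LHCB4.1 and RCA were at 0.32 and 0.05, and the cold-response genes COR15A, COR15B and COR47 at 0.16, 0.23 and -0.09. In the auxin list, IAA29, GH3.3 and WES1 (also known as GH3.5) were at 0.33, 0.12 and -0.08. The anthocyanin genes DFR and UF3GT were at -0.24 and -0.31, and the glucosinolate gene BCAT4 at -0.01. With 1 array left out, the values of RCA, COR15B, PRL, GH3.3 and BCAT4 changed sign, and COR15B ranged from -0.05 to 0.51. Others kept their sign but moved, such as ULT1 (-0.21 to -0.05), GI (-0.30 to -0.07) and COR15A (0.04 to 0.28).

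The root markers EXPA7, EXPA18 and PYK10, which would move with the share of root in the seedlings, had log2 fold changes of 0.40, 0.19 and -0.04, none past the test. With 1 array left out, EXPA7 ranged from 0.12 to 0.69 and PYK10 from -0.14 to 0.05. The 25S ribosomal RNA control probe set, which the test leaves out, read 556 and 841 on the wild type arrays and 2196 and 992 on the knockout arrays. The 3' to 5' signal ratio of the actin control was 1.83 and 2.51 in wild type and 2.49 and 1.90 in the knockout, so both groups held 1 array with a high and 1 with a low ratio. With the older actin control probe sets it was 9.42 and 7.24 in wild type and 5.01 and 4.85 in the knockout, so there the groups did not overlap.

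None of the 30 groups of genes added after the data were seen shifted between knockout and wild type in camera after adjustment, by the preset or by the estimated correlation, nor in fry. At an unadjusted p of 0.05, camera passed 3 groups with the preset correlation and 0 with an estimated one, and fry passed 2. The 3 were the PDF stem, with 6 genes and a mean log2 fold change of 0.37 (camera adjusted p = 0.127), the PUB stem of ubiquitin ligases, with 8 genes and a mean of -0.19 (camera adjusted p = 0.252), and the 12 rapidly induced response genes, with a mean of -0.13 (camera adjusted p = 0.315). The PUB stem and the rapidly induced genes share PUB22, PUB23 and PUB24 (log2 fold changes -0.34, -0.56 and -0.08), so they are not separate groups. With an estimated correlation the camera adjusted p was 0.993 for each of the 3 groups. That version of camera uses only the few residual degrees of freedom of the 4 arrays, so it could hardly pass any group here. For the rapidly induced genes its unadjusted camera p was 0.166, against 0.0424 with the preset, although the estimated correlation was -0.0447. The PDF stem joins PDF1.2b and PDF1.2 with other defensins and with the peptide deformylases PDF1A and PDF1B, and 3 of its 6 genes were above 0. The 69 plastid-encoded genes had a median log2 fold change of -0.05 (-0.097 to -0.0057 with 1 array left out), with 25 above 0 and none changed. The signals were not centred for this. On the log2 scale the mean of the array medians was 0.034 lower in the knockout. After median centring the median of the plastid-encoded genes was -0.017.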

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

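The tests in this part were chosen after the values were seen, except those of scaling, of leaving out single arrays and of the plastid transcripts. Control probe sets take no part in the comparison. Of the 36 at or above the brightness floor, 2 read higher on both knockout arrays than on both wild type arrays and 14 read lower on both. Most of the 14 read bacterial or phage RNA added as a control (bioB, bioC, bioD and cre), so their falls are not changes of plant transcripts. One bioD probe set (AFFX-r2-Ec-bioD-3_at) read 769 and 706 in wild type and 650 and 594 in the knockout. Several of these probe sets read the same added transcript, and other added controls overlapped between the groups. The 25S ribosomal RNA probe set (AFFX-Athal-25SrRNA_s_at) was 2.28-fold higher, mostly through knockout replicate 1. The older actin 5' probe set (AFFX-Athal-Actin_5_r_at) was 1.5-fold higher. Whether the excess of lower over higher controls is beyond chance was not tested, and no group was large enough for an outlier test.

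The count of changed probe sets was set against the other ways to part the arrays. The 4 arrays can be split 2 against 2 in 3 ways, too few for a share under 0.05. Only 1 of the 3 splits, the real one, gave as many as 51 calls in limma, and the highest of the others gave 0, with 1705 and 251 probe sets at an unadjusted p under 0.05 against 834 in the real split. RNA integrity may still differ between the groups. The mean log2 3' to 5' ratio of the actin, GAPDH and ubiquitin controls differed by -0.0495 (SE 0.171, knockout minus wild type), against a mean gap of 0.232 between arrays of a group. The difference lies on the side of the bound set as evidence against this, but by less than its SE, so it stays open. With the older control probe sets the difference was -0.237 (SE 0.0600) against a gap of 0.0809, so it exceeded the gap within groups, mostly through actin, and the 2 sets of controls disagree. The demand that a bound be passed by more than the spread was added to this test after its value was seen.

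AT5G27280 fell from 199 to 9.25, the largest change among the 51 calls. Scaling between arrays is argued against: its log2 fold change nearest 0 under quantile or median normalization was -3.08. A fault of a single array is argued against as well, since the highest adjusted p with 1 array left out was 0.00015. A hypothesis is that AT5G27280 is the gene the labels call CDB1, because the higher of the knockout signals, 14.4, lay below the brightness floor. No annotation used here pairs the names. An unnamed probe set that passed the test met the same condition, at 70.2 and 41.3 in wild type and 7.5 and 13.4 in the knockout. CDB1 may also be read by another of the 8730 probe sets that were not listed. An indirect loss of the AT5G27280 transcript would look alike, so these cannot be told apart.

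The replicate differences ran opposite ways in the groups. The correlation across tested probe sets between replicate 2 minus replicate 1 in wild type and in the knockout was -0.301. The most alike arrays were wild type replicate 1 and knockout replicate 2 (r = 0.984 across probe sets), while knockout replicate 1 was more like knockout replicate 2 (0.982) than wild type replicate 2 (0.979). Scaling is argued against, since the correlation was -0.292 after quantile normalization, and so are plastid transcripts alone, since it was -0.281 over 8627 nuclear probe sets with a single gene. RNA integrity or labelling may contribute: the 3' to 5' ratios split the arrays into the same pairs for 2 of 3 control genes, actin and GAPDH but not ubiquitin, and with the older probe sets for 1 of 3, GAPDH, which does not decide it. The labels name no batch and no biological explanation was tested.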

How the results depend on the processing

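The count of 51 changed probe sets was 48 after quantile normalization, 50 after median centring, 48 and 51 with pseudocounts of 1 and 64, 49 without the intensity trend, 43 with a filter at the 50th percentile and 57 at the 10th, which was added after seeing the data. With both other normalizations 46 of the 51 calls were kept, and all of the 51 that were tested kept their direction under each alternative. As the groups did not overlap for any of the 51, only the other normalizations could have turned a direction. With no filter the count was 0, though 1081 probe sets had an unadjusted p under 0.05. In that fit 14 probe sets had no spread at all and the prior degrees of freedom fell from 8.82 to 3.97, and AT5G27280 had a limma adjusted p of 0.108 (7.69e-16 to 0.108 over all alternatives). At an unadjusted p under 0.05 the count was 834, where chance alone gives about 796. At an adjusted p of 0.1 it was 64. Leaving out 1 array gave 20 to 87 calls, with a lone array assumed to vary like the other group: 20 without knockout replicate 2, 23 without knockout replicate 1 and 87 without wild type replicate 1. Of the 51 calls, 10 held whichever array was left out, and AT5G27280, AT4G29780, AT4G27654 and PDF1.2b are those with a name. Without knockout replicate 1 the share of calls that were higher fell from 52.9% to 21.7%, and without knockout replicate 2 to 35%. The replicate numbers did not pair the arrays. With the replicate number as a block the count was 89, all 51 calls were kept, and 2 list members passed instead of 3. In that fit the prior degrees of freedom rose to 42.2, while 614 probe sets had an unadjusted p under 0.05. The higher count and the limma adjusted p of 7.69e-16 for AT5G27280 may therefore come from that prior. With the block 1 added group shifted (symbol stem PDF), though 0 with an estimated correlation, which had little power here. With the crossed pairing, added after seeing the data, the count was 195 (prior degrees of freedom 14.3), and 6 list members passed instead of 3. Leaving out 1 array gave 2 to 3 list members, and 0 to 2 added groups, the 2 being PDF and ATG without knockout replicate 2, and 0 with an estimated correlation. The cause of these differences between arrays was not tested. Of 345 values of the 25 named genes that had changed, 78 lost the call. None reversed it, which only the other normalizations could have done. Among the named list members that had not changed 4 values gained a call (all of PDF1.2). The planned set test on the fixed lists was not run, because no list had 5 tested members. The brightness of the signals limits what can be said of 6822 probe sets below the floor.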

Other observations

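The list and the test in this part were chosen after the falls of STZ and the other changed genes had been seen, though before the values of the list's own members were. The list holds 12 rapidly induced wound and elicitor response genes and leaves out STZ and the other changed genes, so its members were known not to be among the calls. The lowest were ORA47, a jasmonate-linked transcription factor gene (log2 fold change -0.64, SE 0.159, limma adjusted p = 0.233), PUB23, a ubiquitin ligase gene of immune signalling (-0.56, SE 0.171, limma adjusted p = 0.462), and CML38, a calmodulin-like gene (-0.51, SE 0.142, limma adjusted p = 0.355). At the other end CML43 was at 0.33, CML41 at 0.27 and WRKY22 at 0.16, and 4 of the 12 lay above 0.

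A hypothesis was that such genes are lower as a class in the knockout arrays, as STZ was. The median of the 12 was -0.0684 (SE 0.116). This SE is over the 12 genes, taken as independent, and does not measure the spread between arrays. Camera gave an adjusted p of 0.315 with the preset correlation and 0.993 with an estimated one, which had little power here. A median above -0.1 had been set beforehand as evidence against the hypothesis, and the value with all arrays passes that bound by less than its SE. The demand that it pass by more than its SE was added after the value was seen. With 1 array left out the median ranged from -0.149 to -0.0089, so it lay on both sides of the bound. After median centring, with all arrays, it was -0.034. The members went both ways and genes that had changed were left out, so the hypothesis is neither borne out nor excluded.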
